A study of Mus musculus with 4 samples.

How the data were processed

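RNA was measured in 4 libraries from the lower eyelid of wild-type C57BL/6 mice, an inbred laboratory strain. The lid margin holds the meibomian glands, holocrine glands whose lipid covers the tear film. It also holds skin with hair follicles, conjunctiva, the orbicularis muscle and dermis, so each library mixes the RNA of all of these. Per the labels, 1 library came from each of 4 groups: males of 3 months, females of 3 months, males of 2 years and females of 2 years. The groups of 3 months are called young and those of 2 years old. The labels do not say how many animals went into a library. Per the labels' protocols, lids were excised, frozen in liquid nitrogen and extracted on Qiagen columns, and the libraries were made by Illumina protocols for a HiSeq instrument. The submitters' processing notes name TopHat, Cufflinks and the mouse build mm10, without versions or roles. The counting rule, the strand setting and the gene models are not given in the sources used here.

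The authors deposited 1 table of expressed genes per library, with a gene symbol, its position, an RPKM value and a second column that per the file headers is a raw count. The RPKM values deposited by the authors are normalized for gene length and library total. The tables list genes of at least 0.125 RPKM, so a gene that is missing from a table has a value below that or none. The second column was read as summed base coverage and not as reads: the coverage deposited by the authors sums to 3.82 gigabases in the young male library, 3.78 in the young female, 3.91 in the old male and 3.16 in the old female. Within a gene, the ratio of this coverage to RPKM was the same in every library up to 1 factor per library (0.829 to 1.026 relative to the young male library). No count test was therefore run, read depth is unknown, and no counting interval is given. The old female library has the lowest coverage of the 4, and low genes are measured less precisely in it.

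The authors also deposited 4 tables of their own comparisons of old with young libraries, made per their file names with the program Cyber-T. Per the file headers these tables give both RPKM values, a signed fold, a p-value and a Bonferroni value for each gene. The Bonferroni values deposited by the authors are the p-values multiplied by 23650. The p-values deposited by the authors are printed only to describe those tables. Which replicate values or variance lie behind them, if any, is not given in the sources used here. Every fold in the tables deposited by the authors is at least 2.00.

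Symbols were matched to the GENCODE vM21 annotation of the same build. Of 15816 symbols, 15154 were in the annotation and 99.8% of these overlapped it at the same symbol. Positions are printed as the tables give them, counted from 1. A total of 2 symbols that stood on more than 1 row were left out. Of the 15816 genes listed in at least 1 library, 14281 were listed in all 4, and the 12073 with a mean of at least 1 RPKM over the 4 libraries were analysed. A pseudocount of 1 was added and values were put on a log2 scale, so a log2 ratio understates the change of low genes. Genes that the female libraries do not list, such as those on the Y chromosome, are outside this set.

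With 1 library per group there is no replicate, and no difference between 2 groups has a replicate check or a p-value. For each sex the log2 ratio of old to young is given, and for each age that of male to female, and genes at least 2-fold apart are counted. Effects averaged over the other factor were fitted with limma 3.58.1 in R 4.3.3, with age and sex as terms, moderated variances with an intensity trend and Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom, the difference of the age effect between the sexes, and its p-values measure only the spread among these 4 libraries. Simulated data had 12073 genes, with 100 changed by 1 and another 100 by 2 on the log2 scale. With variances drawn from the fitted prior, the fit recovered 0 of 100 and 0 of 100, for age and for sex. With each gene's own fitted variance it recovered 47 and 98 of 100 for age, with 14 false calls, and 84 and 100 of 100 for sex, with 137 false calls. Errors of averaged log2 differences are the standard errors (SE) of this fit.

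A total of 34 gene lists for tissues, cell types and pathways of the lid were fixed before the data were examined, as were the tests and the alternatives. For a list, the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A median is called outside below percentile 2.5 or above 97.5. This describes these libraries and is not a test across animals. Lists with fewer than 3 analysed members have no percentile. In a simulation with independent noise for each gene, 20 of 20 shifted lists and 1 of 20 unshifted lists fell outside. Members of a real list can move together, so that share does not carry over to the lists here. Of the 32 lists with a percentile, 25 lay outside for age in females and 17 in males. Members past the threshold of the averaged fit are counted over all genes and adjusted over the list alone. Members are measured in the same 4 libraries and can move together, so such counts do not number independent effects.

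Named genes follow a rule set before the data were examined. For age these are the 12 highest and 12 lowest genes by the smaller of the 2 sexes' log2 ratios, leaving out predicted genes with Gm, Rik or LOC names. For sex they are the 6 highest and 6 lowest over the 2 ages, and for the age-by-sex difference up to 4 each way among genes 2-fold apart in opposite directions. Up to 4 members per list with the largest absolute averaged age difference are named, with Xist, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the labels, and Pparg, Krt1, Krt10, Mki67, Awat2, Scd1, Elovl3, Far2 and Soat1 as genes of the gland or of keratinization. Some genes that the rule names are not reported here. Any other gene named was chosen after its values were seen.

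Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 RPKM, quantile normalization, scaling to a common median, unlisted genes set to 0, no intensity trend, no covariate, each library left out in turn, and a p of 0.001 on the authors' tables. Genes in families of near-identical copies are uncertain, since it is not stated how reads shared by copies were counted. These are the Lce, Sprr, Scgb and Defb genes, Saa1 and Saa2, the secretory ribonuclease Ear2 and the ribosomal protein genes, among them Rps4l. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9.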

Results

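The transcriptome of the mouse lower eyelid was compared at 3 months and 2 years of age in males and females, to describe what differs in the lid and its meibomian glands with age. There was 1 library per age and sex. The tables listed 14894 genes in the young male library, 14800 in the young female, 15009 in the old male and 15299 in the old female. Total coverage was 3.82, 3.78, 3.91 and 3.16 gigabases in the same order. The 10 genes with the most coverage took 8.42% to 9.55% of each library. Lipid enzymes of the gland were among the most abundant transcripts, with Scd1, the stearoyl-CoA desaturase, at 3968 RPKM in the young male library and 6123 RPKM in the old female. The sex labels were checked first. Xist, the RNA of the inactive X chromosome, was listed in both female libraries (10.7 and 11.8 RPKM) and in neither male one. The Y-linked genes Ddx3y, Kdm5d and Uty were listed in both male libraries and in neither female one, and Eif2s3y had 32.7 and 41.7 RPKM in the males against 0.149 in the young female library.

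The old female library stood furthest from the others. Its log2 values correlated across genes at Pearson's r of 0.940 with the young female library, while the other pairs without it lay at 0.985 to 0.988. Genes are not independent replicates, so these values describe the libraries. The first principal component held 75.9% of the variance and set the old female library (0.80) against the young female (-0.57), with the young male at -0.10 and the old male at -0.13.

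In females, the medians of the muscle, dermal matrix, complement and lipid synthesis lists were higher at 2 years, and that of the cornified envelope list was lower. Of 12073 genes, 640 were at least 2-fold higher and 400 at least 2-fold lower in the old library. Krt1 and Krt10, the paired keratins of differentiating epidermis, had 490.1 and 732.4 RPKM at 3 months against 6.46 and 17.5 RPKM at 2 years. Their log2 differences were -6.04 and -5.31. Lor, which encodes the cornified envelope protein loricrin, differed by -5.43 and the keratin gene Krt77 by -6.20. With a pseudocount of 5 the counts were 319 and 238, and with a mean of at least 5 RPKM 393 genes were higher. In the other direction, Mmp3, a matrix metalloproteinase, had 0.891 against 29.6 RPKM (log2 4.02), and Col1a1, a chain of type I collagen, 2.30 against 31.6 RPKM (log2 3.30). Lpl, lipoprotein lipase, differed by 3.22 and Soat1, which esterifies cholesterol, by 2.49. The genes lie on the mm10 build as follows: Krt1 on chromosome 15 from 101845426 to 101850786, Krt10 on chromosome 11 from 99385256 to 99389364, and Soat1 on chromosome 1 from 156428108 to 156474328.

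In males, fewer genes were apart, and muscle genes made up a large share of those higher at 2 years. A total of 96 genes were at least 2-fold higher and 25 at least 2-fold lower in the old library. Of the 96, 21 belonged to the skeletal muscle list. Acta1, skeletal alpha-actin, had 51.1 RPKM at 3 months and 148.9 at 2 years, and Mb, myoglobin, 4.64 and 16.9. Sftpd, a collectin of innate defence, had 4.39 and 21.4 RPKM (log2 2.06). Krt1 and Krt10 differed by -0.44 and -0.29 in males, with 380.2 and 512.4 RPKM in the old library. The SD of the log2 differences over all genes was 0.27 in males and 0.60 in females. Neither count has a replicate check, and the pseudocount moves both by more than 1.5 times: with 0.1 the male counts were 193 and 52, and with 5 they were 39 and 11.

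**Figure D1:**
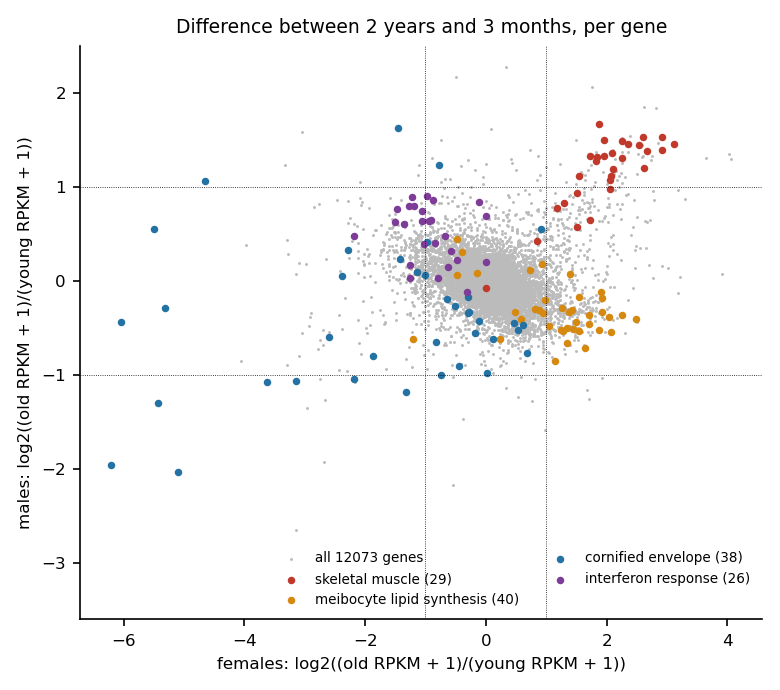
Each point is a gene, with the log2 ratio of old to young RPKM (plus 1) in females on the horizontal axis and in males on the vertical axis. Dotted lines mark 2-fold. Coloured points are members of 4 gene lists. Muscle genes lie to the upper right with medians of 2.05 in females and 1.30 in males, meibocyte lipid genes lie to the right at 1.30 and -0.36, and interferon genes to the upper left at -0.95 and 0.61.

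A small set of genes differed by at least 2-fold the same way in both sexes, 67 higher and 13 lower in the old libraries, where independent lists would share 5.09 and 0.828. With a pseudocount of 0.1 there were 142 and 20 (14.1 and 2.16 if independent), and with 5 there were 23 and 6 (1.03 and 0.217). Of the 67, 21 were in the skeletal muscle list, and of the 13, 7 were in the cornified envelope list. Genes of 1 tissue can move together, so the excess over independent lists does not measure agreement gene by gene. Car3, a carbonic anhydrase of muscle and fat, was higher by 2.33 ± 0.30 (averaged log2 difference, SE, 2 old against 2 young libraries). Sftpd was higher by 1.90 ± 0.18, Mb by 1.77 ± 0.17, Ccl8, a chemokine for monocytes, by 1.96 ± 0.27, Ceacam10 by 1.89 ± 0.26 and the sulfotransferase gene Sult1c1 by 2.15 ± 0.39. Scgb2b2, a secretoglobin, had 4.92 and 4.39 RPKM in the young male and female libraries and 15.7 and 14.2 in the old. The other named genes higher in both sexes were the muscle genes Acta1, Atp2a1, Mybpc2, Myh1 and Tcap, with averaged differences of 1.72 to 2.28. Ear2, a secretory ribonuclease of eosinophils, was lower by 2.90 on the log2 scale (averaged difference -2.90 ± 0.21), with 10.7 and 16.6 RPKM in the young libraries and 0.868 and 0.987 in the old. Wfdc21 differed by -2.31 ± 0.25, Hal, histidine ammonia-lyase of the epidermis, by -1.97 ± 0.39, Flg2, filaggrin-2, by -1.25 ± 0.18, Lor by -3.37 ± 1.06 and Krt77 by -4.08 ± 1.07. The remaining named genes lower in both old libraries were Lce1m, Lce1c, Lce1b, Rps4l, Dkkl1 and Snx31, between -3.56 and -1.62.

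No gene passed the averaged test. With limma, 0 of 12073 genes had an adjusted p under the threshold for age, and the lowest adjusted p was 1. At an unadjusted p under 0.05 there were 353 genes, where evenly spread p-values would give 604. The residual of this fit is the difference between the sexes, and the age ratios spread more in females (SD 0.60 against 0.27). The p-values need therefore not be evenly spread, and 604 is no measure of chance here. In the simulation with variances from the fitted prior no changed gene was recovered either, so the lack of calls does not show a lack of age effects. The call rests on which libraries enter: without the old male library, with the old female alone set against both young, 166 genes passed, 129 higher and 37 lower at 2 years. Across all genes the age ratios of the 2 sexes had a Pearson's r of -0.04 (0.06 with a pseudocount of 0.1 and -0.17 with 5). Their ranks were weakly inverse (Spearman's rho = -0.28, across genes). Of the 1040 genes 2-fold apart in females, 39.4% had the same sign in males, and of the 121 in males 76.0% had the same sign in females.

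Skeletal muscle was the list with the largest medians in both sexes. Of 29 analysed members, 27 were at least 2-fold higher in the old female library and 21 in the old male, and 28 were higher in both. The medians were 2.05 in females and 1.30 in males, each at percentile 100. In the averaged limma fit 27 of 29 passed when adjusted over the list alone (lowest adjusted p 0.0107) and 0 over all genes. The 29 genes were measured in the same libraries and can move together, so the 27 calls are not independent results. Atp2a1, the calcium pump of fast fibres, had 38.7 and 24.1 RPKM in the young male and female libraries and 107.2 and 215.1 in the old. Myh4, the fast myosin heavy chain, had 21.1 and 14.2 against 56.9 and 113.8. Among 5 analysed genes known to rise on denervation or in regenerating muscle the medians were 0.37 and 0.08, both inside the bounds. Sln, sarcolipin, was the 1 member that passed when adjusted over the list alone, at 0.271 and 0.276 RPKM against 2.21 and 1.31. It did not pass under median scaling (adjusted p 0.0515) or quantile normalization (0.0677).

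The medians of dermal matrix and vessel genes were higher in both old libraries. Of 24 analysed fibrillar collagen and matrix genes, 18 were at least 2-fold higher in the old female library and 2 in the old male (7 in the male with a pseudocount of 0.1), with medians of 1.49 and 0.31. Dcn, decorin, had 17.6 against 112.5 RPKM in females and 20.4 against 52.9 in males, and Lum, lumican, 2.55 against 19.4 and 1.46 against 5.28. The medians of complement were 1.49 and 0.56 over 14 genes, with Serping1, the C1 inhibitor, at 2.74 and 1.28. The 5 endothelial genes had medians of 1.38 and 0.35, led by Pecam1 at 1.73 and 0.43, and 4 of the 5 were at least 2-fold higher in females and 0 in males. The senescence list had 0.48 and 0.11 over 16 genes, led by Mmp3 and by Igfbp7 at 2.25 and 0.81. The 5 genes of lacrimal and other exocrine glands had medians of 1.10 and 0.78, with 3 at least 2-fold higher and 1 lower in the old female library. The lower one was Aqp5, a water channel (-1.87 and 0.49), named after its values were seen. Of these 5, 4 passed the limma fit when adjusted over the list alone (lowest adjusted p 0.00427) and 0 over all genes, among them Pigr, which carries IgA across epithelium, at 1.10 and 0.78. Without the old female library, or without the young female library, 2 of the 5 passed. No matrix, complement, endothelial or senescence gene passed limma when adjusted over the list alone (lowest adjusted p 0.0790, 0.0532, 0.0922 and 0.101). For complement 2 did under median scaling and 5 with a pseudocount of 0.1. All these medians lay outside the bounds in both sexes, but without the filter on low values the male senescence median was 0.06, at percentile 90.3 and inside. The muscle genes moved the same way in the same libraries.

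The median of the cornified envelope genes was lower in both old libraries. Of 38 analysed members, 19 were at least 2-fold lower in the old female library and 0 higher, and 7 were lower and 3 higher in the old male. The medians were -0.99 and -0.44; both lay below all random lists. None passed the limma fit, over all genes or adjusted over the list alone. The 16 genes of the basal epidermis had medians of -0.40 and -0.03, the first outside the bounds, with Krt5 at 4112 RPKM in the young female library and 1544 in the old, and 3213 and 3350 in the males. The 37 genes of the hair follicle lay close to 0, at 0.06 in females, inside the bounds, and -0.16 in males, outside them. No hair follicle gene was 2-fold apart with age in either sex. Melanocyte genes had lower medians in both sexes, -0.26 and -0.33 over 12 genes, both outside the bounds. Pmel, a protein of the pigment granule, differed by -0.50 and -0.55.

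**Figure D2:**
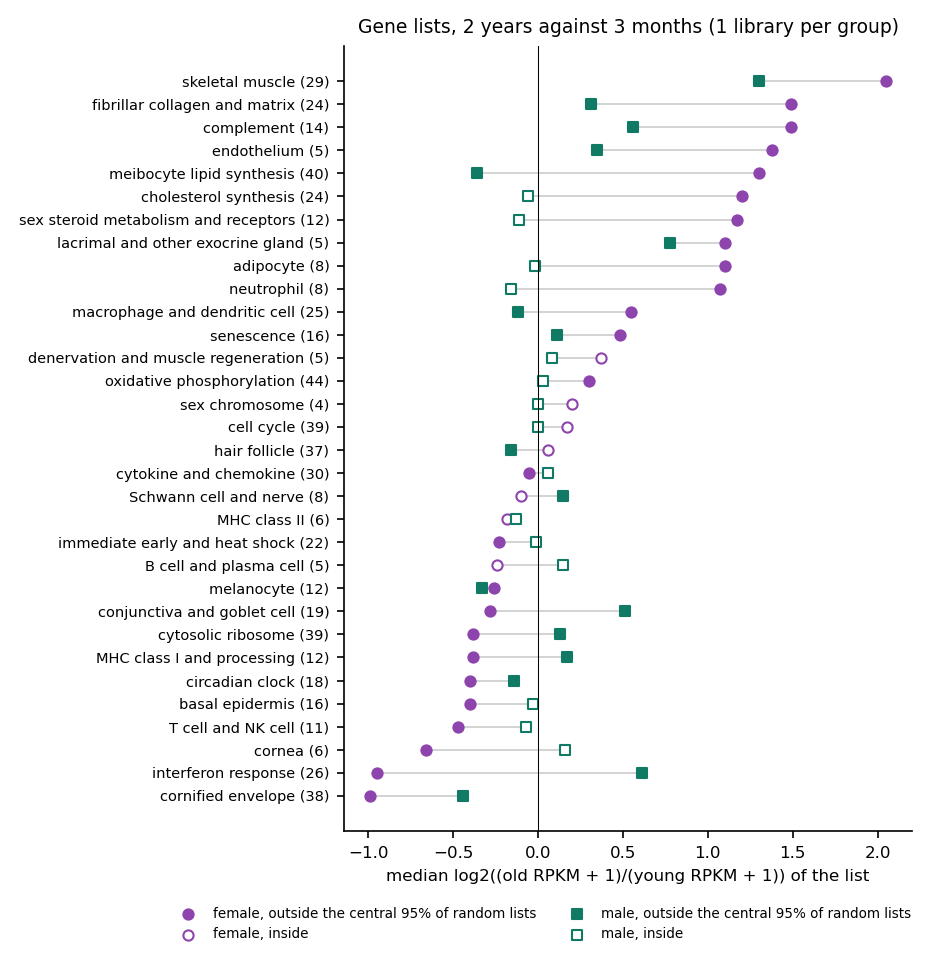
Each row is a gene list with its number of analysed genes in parentheses, and the horizontal axis is the median log2 ratio of old to young RPKM (plus 1). Circles are females and squares males, filled where the median lies outside the central range of 10000 random lists matched on expression. Muscle has the largest medians (2.05 and 1.30) and the cornified envelope list the lowest in both sexes (-0.99 and -0.44). With a pseudocount of 0.1 the interferon list had the lowest female median (-1.06, against -1.01 for the cornified envelope).

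The median of the lipid genes of the gland was higher in the old female library and slightly lower in the old male. Of 40 meibocyte genes for wax esters, fatty acids and lipid droplets, 25 were at least 2-fold higher and 2 lower in the old female library, and 0 were 2-fold apart in males. The medians were 1.30 (percentile 100) and -0.36 (below all random lists). Scd1 had 1493 RPKM in the young female library and 6123 in the old, against 3968 and 3028 in the males. Soat1 had 54.7 and 311.5 against 153.1 and 114.9, Elovl3, a fatty acid elongase, 176.6 and 841.9 against 449.2 and 348.3, and Far2, which makes fatty alcohols for wax esters, 172.6 and 733.4 against 458.5 and 312.4. Awat2, a wax ester synthase, differed by 1.05 and -0.48. Pparg, the receptor that drives lipid cell differentiation, had 9.87 and 34.5 RPKM in females and 23.5 and 16.8 in males. Elovl6 was the exception among the 4 members named by the rule, at -1.20 and -0.62, beside Mgst1 at 1.91 and -0.12. None of the 40 passed the limma fit, over all genes or adjusted over the list alone. In the same comparison of the female libraries the cornified envelope list had the lower median given above.

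Sterol, steroid and adipocyte genes had higher medians in the old female library and medians near 0 in males. Of 24 cholesterol synthesis genes 13 were at least 2-fold higher in the old female library and 0 were apart in males, with medians of 1.20 and -0.06. The 12 genes of sex steroid metabolism had medians of 1.17 and -0.11, with Hsd17b12 at 1.69 and -0.21. The 8 adipocyte genes had medians of 1.10 and -0.02. Cfd, the adipose complement factor D, differed by 2.71 and 0.64, and Car3 was the 1 adipocyte gene that passed limma when adjusted over the list alone (adjusted p 0.0120). All these female medians lay outside the bounds and these male medians inside.

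Of 26 interferon-induced genes, 12 were at least 2-fold lower in the old female library and 0 were apart in males, with medians of -0.95 and 0.61, both outside the bounds. Isg15, a ubiquitin-like protein, had 57.5 RPKM in the young female library, against 16.8 in the young male, 23.8 in the old male and 11.8 in the old female. The medians of MHC class I and its processing were -0.38 and 0.17, both outside, and those of MHC class II -0.18 and -0.13, both inside. The 11 T cell and NK cell genes had medians of -0.47, outside, and -0.07, inside, with the granzyme gene Gzma at 12.7 RPKM in the young female library and 1.52 to 3.23 in the others. Without the filter the male T cell median was -0.17 over 23 genes, outside. The 25 macrophage and dendritic cell genes had 0.55 and -0.12, both outside (the male median without the filter was -0.05, inside), and Cd207, a lectin of Langerhans cells, was lower in both old libraries by -1.32 and -0.83. The 8 neutrophil genes had 1.07, outside, and -0.16, inside. The 5 B cell and plasma cell genes had -0.24 and 0.15, both inside, although Igj, the joining chain of IgA and IgM, had 0.786 and 8.19 RPKM in females and 1.07 and 2.91 in males. Without the filter the female B cell median was -0.18 over 8 genes, outside. Of 30 cytokine and chemokine genes 7 were at least 2-fold higher and 6 lower in the old female library, and 4 higher in the old male, with medians near 0 (-0.05, outside, and inside without the filter, and 0.06, inside). Ccl8, Ccl11 and Cxcl5 were higher in both old libraries, Ccl11 by 1.69 and 1.18 and Cxcl5 by 0.84 and 1.07. Kit was the 1 mast cell gene analysed, at -0.86 and -0.11, and Alas2 the 1 erythroid gene, at 0.16 and 0.45.

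The conjunctival list was mixed. Of 19 genes 5 were at least 2-fold higher and 5 lower in the old female library, with medians of -0.28 in females and 0.51 in males, both outside the bounds. Krt13, a keratin of the mucosal surface, had 3842 RPKM in the young female library and 392.3 in the old, against 2286 and 3080 in males. Of the 19, 7 were higher in both old libraries, among them Spdef, a transcription factor of goblet cells, by 1.14 and 0.83, and Tff1, a mucus-associated trefoil peptide, by 1.24 and 0.66. None passed limma when adjusted over the list alone, and 1 did without the filter on low values. The 6 corneal genes had medians of -0.66, outside, and 0.16, inside. Medians closer to 0 were found for cell cycle genes (0.17 and 0.00, inside), with Mki67, a marker of dividing cells, at 0.68 and -0.07. Oxidative phosphorylation had 0.30, outside, and 0.03, inside. Cytosolic ribosome genes had -0.38 and 0.13, both outside, and immediate early and heat shock genes -0.23, outside, and -0.01, inside. The Schwann cell and nerve list had -0.10, inside, and 0.15, outside. Clock genes, which follow the time of day, had -0.40 and -0.14, both outside, with Dbp at -1.23 and -0.55. The 4 analysed genes of the sex chromosome list had 0.20 and 0.00, both inside.

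**Figure D3:**
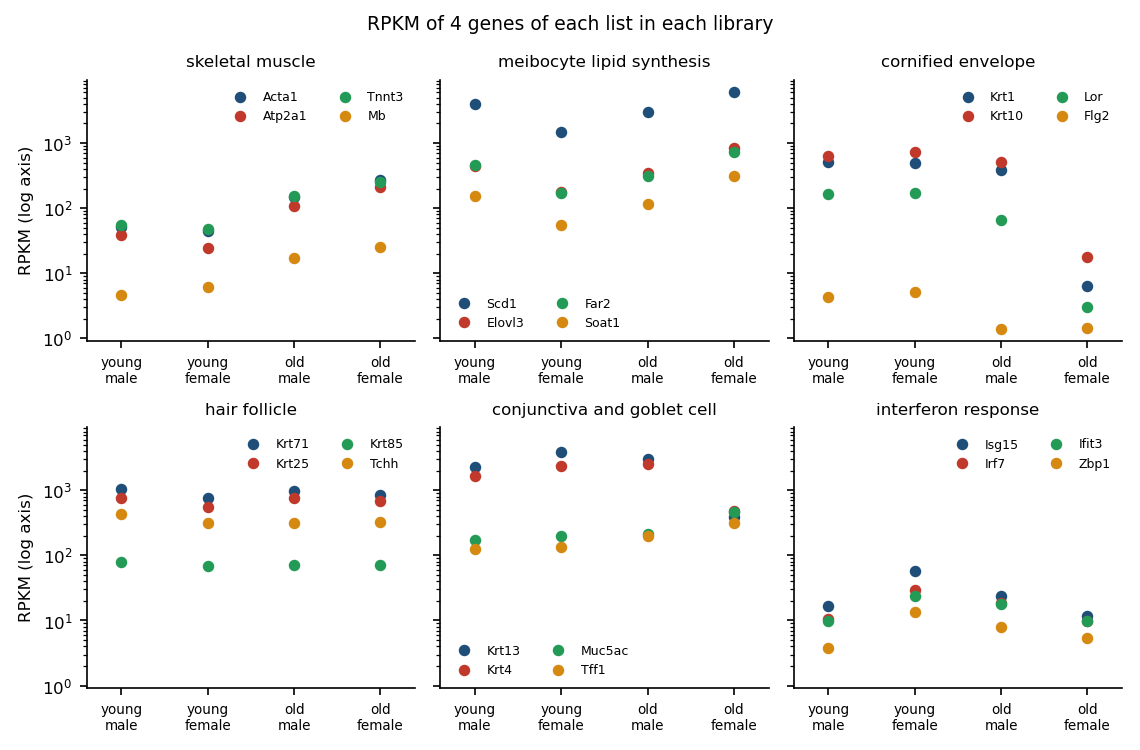
RPKM in each of the 4 libraries, on a log axis, for 4 genes of each of 6 lists, 1 point per gene and library. The hair follicle genes and some others were chosen after their values were seen. Krt1 spans 380.2 to 514.7 RPKM in 3 libraries and 6.46 in the old female, Acta1 is 44.4 and 51.1 in the young libraries and 148.9 and 274.7 in the old, and Isg15 is highest in the young female library at 57.5.

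The sexes were compared at each age. At 3 months 112 genes were at least 2-fold higher in the male library and 42 in the female, and at 2 years 227 and 212. The counts move with the pseudocount, to 203 and 73 at 3 months with 0.1 and 57 and 18 with 5. At 2 years the balance turns, with 296 and 403 at 0.1 and 141 and 91 at 5. Sprr2d, a cornified envelope precursor, had 28.1 and 24.4 RPKM in the males and 5.42 and 3.12 in the females at the 2 ages. Defb3, a beta-defensin, had 5.62 and 5.99 against 1.38 and 1.23, S100a8, a subunit of calprotectin, 90.4 and 103.1 against 16.8 and 37.8, and S100a9, its partner, differed between male and female by 1.69 and 1.44 on the log2 scale. Uox, urate oxidase, differed by 1.01 and 1.19, and Krt16, a keratin of stressed epidermis, had 128.6 and 170.9 against 65.7 and 33.0. In the other direction Serpinb6d had 13.8 and 38.3 RPKM in the females against 3.49 and 3.44 in the males, and Lman1l 12.3 and 28.3 against 6.77 and 12.2. Crisp1 differed between male and female by -0.98 and -0.64. Car3, Gzma and the microRNA gene Mir3091 were also higher in the female libraries at both ages.

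No gene passed the averaged test for sex. With limma, 0 of 12073 genes passed and the lowest adjusted p was 1. At an unadjusted p under 0.05 there were 63 genes, where evenly spread p-values would give 604. As for age, that number is no measure of chance here, and the lack of calls does not show a lack of sex effects. Without the young female library 18 passed, 10 higher and 8 lower in males. S100a8 and S100a9 passed when adjusted over the neutrophil list alone (lowest adjusted p 0.0161), and Sprr2d did over the cornified envelope list alone (0.0111). S100a8 and S100a9 were the only 2 of the 8 neutrophil genes at least 2-fold higher in males at both ages. The median of the 8 (male against female) was 0.60 at 3 months and -0.63 at 2 years, so these calls do not describe the list. Only 2 of the 32 lists with a percentile lay outside the bounds on the same side at both ages. These were complement (male against female, -0.13 at 3 months and -0.82 at 2 years, the first inside the bounds without the filter, at -0.05) and the sex chromosome list (-0.35 and -0.57), whose 4 analysed members are X-linked. Another 9 lists lay outside on opposite sides at the 2 ages. Meibocyte lipid genes were higher in the male library at 3 months (median 0.94) and lower at 2 years (-0.73), cholesterol genes had 0.73 and -0.60, and interferon genes -1.06 and 0.44.

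The age difference went in opposite directions in the sexes, by at least 2-fold in each, for 10 genes (20 with a pseudocount of 0.1 and 4 with 5). Acoxl, Saa1 and Saa2 were higher with age in females and lower in males. Acoxl, an acyl-CoA oxidase-like gene, had log2 differences of 1.71 and -1.26, and the acute-phase genes Saa1 and Saa2 had 1.67 and -1.16, and 1.92 and -1.04. Another 7 genes were lower with age in females and higher in males. Among them Lce3a differed by -4.65 and 1.06, Lce3b by -3.05 and 1.58, Psca, a surface antigen of mucosal epithelia, by -3.33 and 1.23, and BC100530 by -2.08 and 1.05. The difference between the sexes has no residual in this design and was not tested.

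The authors' own comparisons were set beside these values. The authors' deposited table of genes higher at 2 years holds 1983 genes for females and 673 for males, and the table of genes lower at 2 years 750 and 315. The largest p in the authors' deposited tables is 4.23e-09, so a stricter threshold of 0.001 leaves every table as it is. Of the listed genes that were also analysed here (792, 400, 186 and 60 in the order of higher and lower in females, then males), all had the same direction, and 518, 278, 79 and 22 were at least 2-fold apart with a pseudocount of 1. The shared direction was fixed in advance and is no check, since the authors' deposited tables hold the same RPKM values as the library tables. In the authors' deposited table Col1a1 has a signed fold of 13.7 in females and 2.08 in males, and Ear2 one of -16.8 in females and -12.4 in males. The highest RPKM in the tables is 113.8. Summed over the 4 comparisons, so that a gene apart in both sexes counts in each, the authors' deposited tables hold all 1186 entries with a 2-fold RPKM ratio and a higher value of 1 to 10 RPKM. From 10 to 100 RPKM they hold 567 of 602, and above 100 RPKM 4 of 237. Krt1, Krt10, Scd1, Elovl3, Far2 and Soat1, all above 100 RPKM, are in none of them.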

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

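All tests of explanations in this part were chosen after the results were seen. The differences between the sexes given here were not tested, since each rests on 1 library per group. They stand here because the age difference went one way in females and the other way in males.

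Among gene lists with medians outside the range of random lists in both sexes, the median log2 age difference in females minus that in males was 1.66 for meibocyte lipid synthesis and 0.67 for macrophages and dendritic cells, whose male median lay inside that range without the filter on low values (-0.05, percentile 19.7). It was -1.56 for the interferon response, -0.79 for conjunctiva and goblet cells, -0.55 for MHC class I and -0.51 for the cytosolic ribosome. For single genes it was 2.97 for Acoxl, 2.96 for Saa2, 2.84 for Saa1, -5.71 for Lce3a, -4.62 for Lce3b, -4.57 for Psca and -3.13 for BC100530. The female part of the interferon difference (median -0.95) goes with the young female library, which held the highest value of the 4 for Isg15, Rtp4, Oas3 and Ifi44. The male part (median 0.61) does not involve that library.

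In the old female library meibocyte lipid genes were higher than in the young female library while Krt1, Krt10 and other surface keratinization genes were far lower. Scaling is argued against as the cause of the lipid part, whose lowest median under median scaling or quantile normalization was 1.24. Loss of surface epithelium alone would raise the rest of the lid alike, but the lipid median exceeded that of the hair follicle genes by 1.25. Their quartile ranges did not meet (0.79 to 1.67 against -0.12 to 0.27). Other parts moved unevenly too. In females the muscle, matrix and endothelial medians were 2.05, 1.49 and 1.38, and the nerve and melanocyte medians -0.10 and -0.26. The 8 nerve genes ranged from -2.04 to 1.39, so their median does not show how nerve itself moved. The lipid rise (median 1.30) therefore stood apart from the hair follicle genes but not from muscle, matrix or vessel genes. An equal loss of all surface epithelium would lower genes made only there by about 1 factor. The log2 RPKM ratios of the keratinization genes had an interquartile range of 3.33, against 0.63 for the same genes between the young libraries. This cannot exclude an equal loss, since members also made elsewhere in the lid would fall less. The 1 pair of young libraries also gives no error for that range. The lipid rise does not rest on the old female library alone, since lipid genes were also low in the young female library. Their median (male against female) was 0.94 at 3 months and -0.73 at 2 years. At 3 months 18 of 40 were at least 2-fold higher in the male library and 0 lower, and at 2 years 1 and 11. Loss of only part of the surface epithelium stays open and untested. So does a glandular share that is low in the young female piece or larger in the old one. A change of the glands or the epidermis with age in females stays open and untested too.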

How the results depend on the processing

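The list-alone counts under other settings were added after seeing the data; the other alternatives were planned. No paired analysis was possible because each group holds 1 library. With limma, the averaged age effect gave 0 genes in every setting with all 4 libraries and 0 to 166 when 1 was left out (166 without the old male library); for sex the range was 0 to 18 (18 without the young female library). Fits of 3 libraries hold no second factor and assume that the lone library of an age or sex varies like the others. With a pseudocount of 0.1 genes at least 2-fold apart numbered 193 higher and 52 lower in old males, 203 and 73 by sex in the young, and 296 and 403 by sex in the old, where the female side became the larger; 162 went the same way in both sexes and 20 opposite ways. With a pseudocount of 5 the counts were 319 and 238 (age, females), 39 and 11 (age, males), 57 and 18 (sex, young) and 141 and 91 (sex, old), with 29 the same way and 4 opposite. By construction a higher pseudocount shrinks the ratios of low genes. With a mean of at least 5 RPKM, which tests fewer genes, 393 were higher in old females, 128 were lower in males among the old and 51 went the same way. Without a filter 1 list, not 2, lay outside on 1 side at both ages, since the complement median in the young (male against female) was -0.05, inside, and the median of the T cell list in the old (male against female) was -0.09, not 0.14, since members below 1 RPKM enter. The averaged Car3 sex difference was 0.19 without the old female library and -2.62 without the young female; by construction age enters these, as the lone female library is set against both male ones. List medians were run under median scaling, quantile normalization, a pseudocount of 0.1 and no filter: 518 kept direction and call, 17 were stronger, 8 weaker and 1 reversed. Median scaling moves all genes of a library alike, so by construction it cannot change a percentile. The calls kept under it are therefore no check. Weaker without a filter were the age medians of senescence (0.06) and macrophages (-0.05) in males and of cytokines in females (-0.03), and the sex medians in the old of senescence (-0.12) and cornea (0.24). Weaker under quantile normalization were the nerve list in males (0.15) and the B cell list by sex in the old (0.28). In males the neutrophil median lay outside under quantile normalization (-0.25) and a pseudocount of 0.1 (-0.32), and that of steroid genes under quantile normalization (-0.17). Without a filter the age median of the T cell list in males (-0.17) and that of the B cell list in females (-0.18) lay outside. The calls of the muscle list, adjusted over the list alone, numbered 20 to 28, and those of the exocrine list 2 to 5. The 1 call of the denervation list was lost under median scaling and quantile normalization, and complement, with 0 calls, had 2 under each of these and 5 with a pseudocount of 0.1. Cytokines, with 0 calls, had 2 under each of these, a pseudocount of 0.1 and no filter. Without a filter conjunctiva, mast cell and erythroid lists had 1 each, not 0. For sex the adipocyte list had 1, not 0, with a pseudocount of 0.1. A p of 0.001 on the authors' tables removed nothing and says nothing of stability. Low genes are limited most in the old female library, with 3.16 gigabases.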

Other observations

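All tests of explanations in this part were chosen after the results were seen.

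Genes outside the analysed set add to the description of the old lids. A total of 201 genes were listed in both old libraries and in neither young one, against 65 in both young libraries and neither old one. None of the 201 exceeded 5.55 RPKM, and the old female library also lists the most genes, so a gene near the lowest listed value can be missing from a table for small differences. Of the 201, 12 belong to the lists fixed before the data were examined. They include Cxcl13, a B cell chemokine (1.87 RPKM in the old male library and 2.32 in the old female), Myl2, the slow muscle myosin light chain (1.04 and 1.16), Cdkn2a, the p16 and Arf locus of senescent cells (0.323 and 1.40), Cpa3, a mast cell protease (0.347 and 0.956), and Col11a1 (0.336 and 0.814). Of the 65, 1 is in a list, Cd8b1 of cytotoxic T cells (0.349 and 0.333 in the young libraries). These genes were chosen after their values were seen.

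With a gene missing from a table taken as lower, 30.4% of the 3743 genes outside the analysed set were higher in both old libraries and 14.4% lower in both. Among list members outside the set, 10 of 10 matrix genes, 9 of 11 endothelial genes and 6 of 6 macrophage genes were higher in both, while the median of the analysed macrophage genes was -0.12 in males. Of 7 mast cell genes 4 were higher in both, while Kit, the 1 analysed, was lower in both (-0.86 and -0.11). Mcpt4, a mast cell chymase named after its values were seen, had 0.166 and 0.266 RPKM in the young male and female libraries and 0.788 and 2.55 in the old. Of 18 T cell genes outside the set, 10 were lower in both old libraries and 1 higher.

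Skeletal muscle genes were higher in both old libraries. Scaling is argued against, since the lowest median of the list in either sex was 1.28 under median scaling or quantile normalization. More muscle in the excised piece would raise its genes by about 1 factor, and in males their log2 ratios had an interquartile range of 0.25, no wider than the 0.50 of the same genes between the young libraries, so a larger share of muscle may account for the male values. In females the range was 0.86, longer genes had larger ratios (Spearman's rho 0.73 across the 29 genes), and a length effect over the whole library is argued against by a rho of -0.03 over all genes. A larger share of muscle in the female piece cannot be told apart from a change within the muscle, since 1 pair of young libraries gives no error for that range, and age itself stays open and untested.

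Abundant genes are missing from the authors' deposited tables, which, summed over the 4 comparisons, hold 1.69% of the entries with a 2-fold RPKM ratio above 100 RPKM and 94.2% of those from 10 to 100 RPKM. Different input values are argued against: of 6057 values in the authors' deposited tables that a library also lists, 0 differed from the library's RPKM by more than 0.1%. A filter or test of the authors that takes few genes above about 100 RPKM may account for this. That restates the pattern and was not tested apart from it. In the authors' deposited tables genes with nearly the same pair of RPKM values differed in p by a median of 0.10 to 0.14 on the log10 scale, against 1.02 to 1.32 for random pairs. No biological explanation was tested.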
